A study of Homo sapiens with 6 samples.

How the data were processed

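RNA-seq libraries were made from IMR90 cells, a normal human lung fibroblast line, expressing the oncogenic RAS form named RASV12 and transfected with a miR-146a mimic that carries psoralen and biotin. Per the labels' protocols, cells were selected with 1.5 ug/ml puromycin for 3 days, seeded on day 10 after infection and transfected 24 hours later. The labels put 3 libraries in a miR-CLIP group and 3 in an Input group. AGO2 immunoprecipitation followed by biotin/streptavidin purification is described once for all samples, and how Input RNA was drawn off is not given in the sources used here. Libraries were depleted of ribosomal RNA and prepared with the KAPA RNA HyperPrep Kit with RiboErase, per the labels' protocols. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

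The deposited table gives 1 signal value per gene and library, and it was described from its values. Every value was a whole multiple of its column's smallest value above 0, within a tolerance of 1e-06, for 100% of values in each of the 6 libraries. This is the form of gene read counts divided by 1 size factor per library by the authors, referred to here as normalised read counts. 1 read was worth 0.612, 0.832 and 0.867 in Input libraries A, B and C, and 1.03, 0.993 and 1.25 in miR-CLIP libraries A, B and C. The submitters' processing notes name Trimmomatic 0.35, STAR 2.5.1b, DESeq2 1.22.2 and build GRCh38, with no role or order. The program that counted reads, its strand setting and the annotation release are not given in the sources used here. Per the file headers, the authors also deposited a linear fold change (a ratio of miR-CLIP over Input), a p-value and an adjusted p-value for each gene.

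The table held 18234 genes. Of their identifiers, 18143 were found in GENCODE release 29, and all 16967 that also shared the version number had the same coordinates there. Gene classes, transcripts and 3′ UTRs were taken from that release. The table was a partial one: it held 78.2% of the release's protein-coding genes with initials A to L and 8.70% of those with initials M to Z, and 22 of the latter had enough signal to be tested. TRAF6, MIR146A, MALAT1 and NEAT1, which were to be named wherever measured, were not analysed here for that reason, nor was MIR3142HG under that symbol. The rows held 12771968, 9379996 and 9295325 reads in Input A, B and C, and 9378463, 8088221 and 6847837 in miR-CLIP A, B and C. These totals cover the rows held, not the whole libraries. Genes with a read numbered 11930, 10905 and 10204 in Input A, B and C, against 8940, 11137 and 7329 in miR-CLIP A, B and C.

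The design fixed before the data were examined assumed read counts tested with edgeR, and gave limma as the test to use if the table held normalised values, as it did. The main test was therefore limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), two-sided, for genes with a value of at least 1 in at least 3 libraries, with Benjamini-Hochberg adjustment over the 8506 genes kept and a threshold of 0.05. The pseudocount of 1 shrinks the fold changes of low genes. All 6 libraries entered the fit with group as the only term, and differences are miR-CLIP minus Input. On simulated reads of 6343 genes drawn from the real means and dispersions, with 100 genes changed at each fold, this test recovered 5% of 2-fold and 35% of 4-fold changes with 3 libraries against 3, with 1 false call. With miR-CLIP library B left out, on 6485 simulated genes, it recovered 31% and 69%, with 11 false calls. The simulation drew each gene independently, with the same dispersion in both groups. In the real libraries the median SD of log2 values was 0.27 in Input and 0.77 in miR-CLIP, so these rates may not carry over.

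Of 23 gene lists fixed before the data were examined, 17 had at least 3 tested members. Because the table held few protein-coding genes with initials M to Z, lists of such genes were tested largely through members with initials A to L. They were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over the 17 lists. The lists of abundant structural RNAs, mitochondrially encoded transcripts, ribosomal protein genes, small nucleolar RNAs, spliceosomal snRNAs and microRNA hairpin genes had 0 tested members and are not analysed further. Long non-coding RNAs (lncRNAs) were compared with protein-coding genes by Fisher's exact test on calls, which runs across genes that are not independent replicates. Medians of classes were also set against coding genes matched over 10 bins of mean log2 value.

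Sites for miR-146a were searched as the 7-mer AGTTCTC (7mer-m8 site) in the longest annotated 3′ UTR of each of 6294 tested protein-coding genes. The mean log2 fold change of genes with a site minus that of genes without one was ranked among all 299 other 7-mers of the same base composition without CG. As a check of the code, the real log2 fold changes were shuffled over genes. With a shift of 0.3 added to genes with the site, the test gave back 0.301, above 100% of control 7-mers. With no shift it gave a value above 34.1% of them. Shuffling removes any trend with 3′ UTR length, so this check does not measure how often a small rank p arises in the real data.

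By the rule fixed in advance, the text names up to 12 genes higher and 12 lower among those past the threshold, of which there were none, up to 6 and 4 such lncRNAs, up to 4 members with the smallest p in each list, and IRAK1, TRAF6, AGO2, HRAS, MIR146A, MIR3142HG, MALAT1 and NEAT1 where measured. Clone-based names and pseudogenes were passed over. Other genes are said to have been chosen after their values were seen.

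Alternatives fixed before the data were examined were other scalings (RLE, library size alone, upper quartile, TMM without structural RNAs), no filter, a stricter filter of at least 1 CPM in all 3 libraries of a group, pseudocounts of 0.1 and 5, DESeq2 1.42.0 and limma-voom on the recovered reads, a threshold of 0.01, a block by column letter, leaving out each library in turn, other site types and the coding sequence. Chosen after seeing the data were edgeR 4.0.16 on the recovered reads with and without miR-CLIP library B, TMM factors over all genes, library weights, and a correction for GC content and transcript length (mgcv 1.9.3) with and without miR-CLIP library B, and, for the site test, removal of 3′ UTR length and GC share by a least-squares fit with cubic terms. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. Sample columns carry letters while titles carry replicate numbers, so columns were matched to groups only and libraries are named by letter.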

Results

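The series asked which RNAs are bound by miR-146a in fibroblasts driven into senescence by oncogenic RAS. In miR-CLIP, RNA held by AGO2, the protein that carries microRNAs to their targets, is immunoprecipitated, and RNA crosslinked to the psoralen and biotin of the microRNA mimic is then purified on streptavidin. The table held 3 miR-CLIP and 3 Input libraries of IMR90 cells expressing RASV12, with between 6847837 and 12771968 reads in the rows held. Values below are normalised read counts on build GRCh38, given as mean ± SD over n = 3 libraries, and log2 fold changes are miR-CLIP minus Input ± SE.

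No gene passed the threshold in the comparison of miR-CLIP with Input. IRAK1, a kinase of interleukin-1 receptor signalling and a known miR-146a target with 2 copies of the 7mer-m8 site in its 3′ UTR (chromosome X, 154010500 to 154019980), had 1420 ± 303 normalised read counts in Input and 2913 ± 1142 in miR-CLIP. Its log2 fold change was 0.97 ± 0.37, with values of 3655, 1599 and 3486 in miR-CLIP libraries A, B and C. AGO2 (chromosome 8, 140520156 to 140635619) had a log2 fold change of 0.89 ± 0.51, from 5190 ± 710 in Input to 11414 ± 7400 in miR-CLIP. HRAS (chromosome 11, 532242 to 537287), a member of the RAS gene family, had 8531 ± 716 in Input and 12078 ± 4242 in miR-CLIP, a log2 fold change of 0.43 ± 0.34. The limma adjusted p was 0.611 for IRAK1 and AGO2 and 0.635 for HRAS. Without miR-CLIP library B, the log2 fold change was 1.35 for IRAK1, 1.50 for AGO2 and 0.77 for HRAS, with limma adjusted p of 0.00384, 0.00489 and 0.0174. In that fit 67 of the 87 genes picked for naming passed, and 2442 of all 8506 tested genes did. Most named genes were picked for a small p or for groups that did not overlap in these data, so their higher share is no separate support. Over all alternatives the adjusted p of IRAK1 ran from 0.00211 to 0.976, that of AGO2 from 0.00218 to 0.976 and that of HRAS from 0.00588 to 0.976.

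Of 8506 genes tested with limma, 0 were higher and 0 were lower at adjusted p 0.05, and the smallest adjusted p was 0.611. At an unadjusted p under 0.05, 204 genes were higher and 344 lower. No gene passed with edgeR, DESeq2 or limma-voom on the recovered reads either, where 304, 495 and 162 genes were higher and 150, 188 and 293 lower at an unadjusted p under 0.05. In the authors' deposited table, the smallest adjusted p was 0.933, and of 513 genes with a p under 0.05, 341 had a fold above 1 and 172 a fold below 1. The groups did not overlap for 480 genes higher and 623 genes lower in miR-CLIP, or 13% of genes tested, where chance gives 10% for 3 libraries against 3. Without miR-CLIP library B, 1069 genes were higher and 1373 lower with limma, and edgeR without it called 1109 and 1298. Of these, 2201 genes were called by both, all 2201 in the same direction. Library B lay on the same side of the Input mean as A and C in 766 of the 2442 genes called by limma without it (31.4%).

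The genes with the smallest p among those whose groups did not overlap, chosen after their values were seen, spanned several functions. Higher in all 3 miR-CLIP libraries were ATP5L, a subunit of mitochondrial ATP synthase (chromosome 11, 118401154 to 118431496), with 1427 ± 37.9 in Input and 3453 ± 578 in miR-CLIP, and HOMER3, a scaffold protein of glutamate receptor signalling (chromosome 19, 18929201 to 18941261), with 283 ± 40.8 and 883 ± 271. Their log2 fold changes were 1.26 ± 0.24 and 1.60 ± 0.31. The carbonyl reductase CBR1 had 1.00 ± 0.27, CHAC1, which degrades glutathione, 1.10 ± 0.31, COPRS 1.12 ± 0.32, CCDC57 1.49 ± 0.44, the cap-binding protein EIF4E2 1.12 ± 0.33 and the histidyl-tRNA synthetase HARS, which overlaps a neighbouring paralog, 1.13 ± 0.34. Lower in all 3 were C5orf51 (chromosome 5, 41904188 to 41921636), with 1463 ± 40.3 in Input and 533 ± 303 in miR-CLIP, the endosome tether EEA1, with 1909 ± 567 and 818 ± 233, and the sialomucin CD164, with 4363 ± 1296 and 1812 ± 731. Their log2 fold changes were -1.60 ± 0.38, -1.22 ± 0.32 and -1.30 ± 0.35. CCDC186 had -1.24 ± 0.32, the ribosome biogenesis factor KRR1 -1.20 ± 0.32, LIN7C -1.05 ± 0.28, the Golgi protein BLZF1 -1.19 ± 0.32 and the dynein light chain DYNLT3 -1.90 ± 0.51. Each of these 16 genes had a limma adjusted p of 0.611. The genes named here as higher had 0 copies of the 7mer-m8 site in the 3′ UTR. Among those lower, KRR1 and LIN7C had 1 copy each and the others 0.

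**Figure D1:**
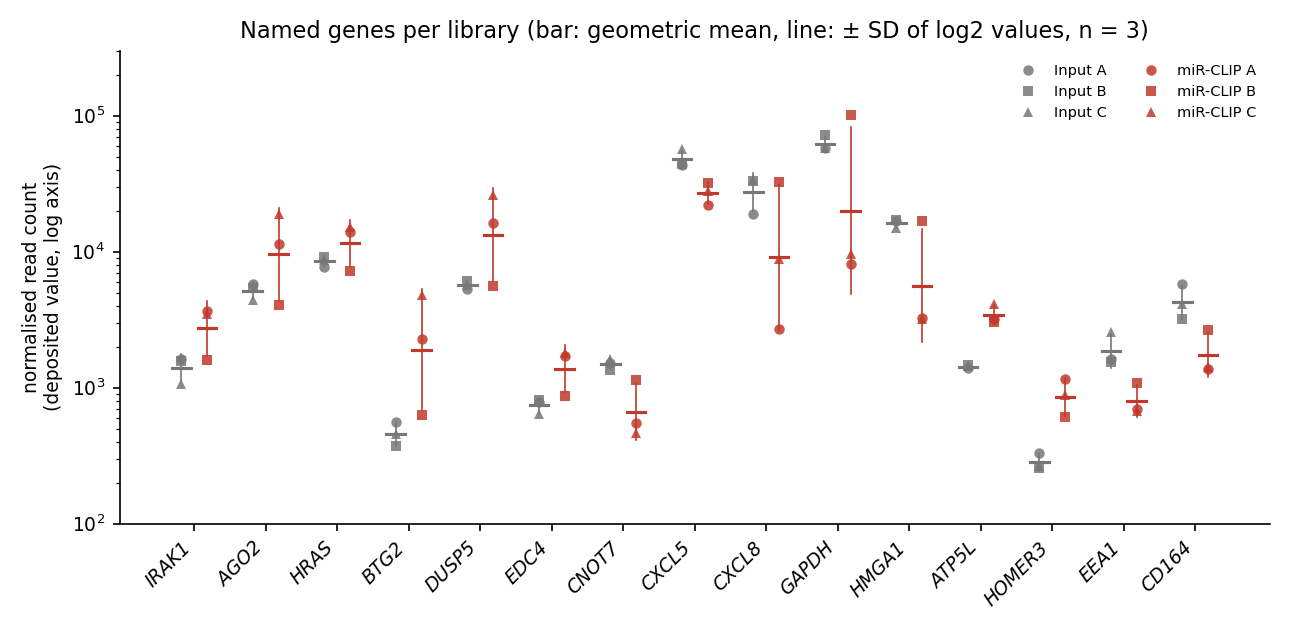
Normalised read counts (log axis) of 15 named genes in each of the 3 Input libraries (grey) and 3 miR-CLIP libraries (red), with the geometric mean as a bar and ± SD of log2 values as a line. For IRAK1, AGO2, BTG2 and DUSP5 the square of miR-CLIP library B sits near the Input points, while ATP5L and HOMER3 lie above Input in all 3 miR-CLIP libraries and CXCL5, EEA1 and CD164 below it.

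The 6 libraries did not fall into the 2 groups of the labels. Across genes, which are not independent replicates, miR-CLIP library B had Pearson r of 0.979, 0.983 and 0.973 with Input A, B and C, and 0.929 and 0.911 with miR-CLIP A and C. The Input libraries had r between 0.980 and 0.987 with each other, and miR-CLIP A and C had 0.942, while miR-CLIP A had 0.952, 0.946 and 0.940 with Input A, B and C. The first principal component held 59.8% of the variance and placed the Input libraries at -32.4, -35.2 and -33.0, miR-CLIP B at -52.5, miR-CLIP A at 43.8 and miR-CLIP C at 109. The second held 22.2% and set miR-CLIP A, at 72.8, apart from miR-CLIP C, at -41.4. The median SD of log2 values within a group was 0.27 in Input and 0.77 in miR-CLIP. No pair of libraries agreed within the sampling noise of read counting alone, since chi-square per degree of freedom was at least 22.3. Variation from the preparation of separate libraries is not part of that noise.

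Transcript length went with the same division. In the shortest of 4 equal bins of tested protein-coding genes, 213 to 2156 nucleotides, the median log2 difference from the Input libraries was -0.85 in miR-CLIP A, 0.48 in B and -0.93 in C. In the longest bin, 5298 to 33679 nucleotides, it was 0.56, -0.27 and 0.35. Over 8469 genes the Spearman correlation of that difference with transcript length was 0.361 in A, -0.372 in B and 0.334 in C, against -0.00136, -0.107 and 0.0477 for each Input library set against the other 2.

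**Figure D2:**
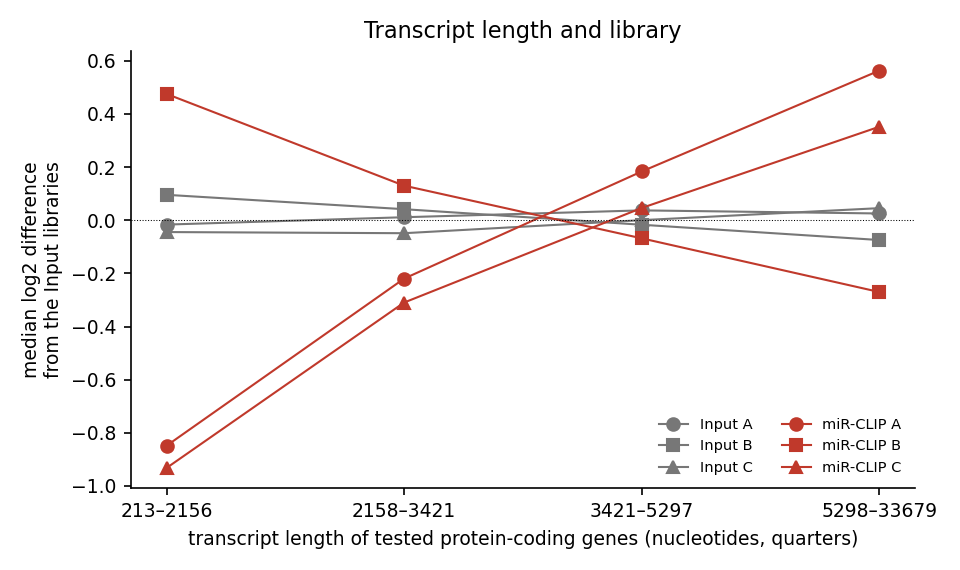
Median log2 difference from the Input libraries (vertical axis) over 4 bins of transcript length in nucleotides (horizontal axis) for tested protein-coding genes, 1 line per library, with Input in grey and miR-CLIP in red. The lines of miR-CLIP A and C climb from -0.85 and -0.93 to 0.56 and 0.35, that of miR-CLIP B descends from 0.48 to -0.27, and the Input lines stay near 0.

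Among the fixed gene lists, 3 passed by camera with the preset correlation and in neither other list test. Replication-dependent histone genes and secreted factors of the senescence-associated secretory phenotype (SASP) had lower values in miR-CLIP, and microRNA pathway genes higher ones. In miR-CLIP library B the medians of all 3 lists ran the other way. The 65 tested histone genes had a median log2 fold change of -1.56, against -0.13 over all tested genes, with 60 negative and 5 positive values. Those with the smallest p were HIST1H4I at -3.04 ± 1.20, HIST1H2BO at -3.61 ± 1.48, HIST1H2AK at -2.87 ± 1.25 and HIST1H1T at -1.97 ± 0.74. HIST1H1T was low, with 5.12 ± 2.99 in Input and 0.688 ± 1.19 in miR-CLIP. The 28 SASP genes had a median of -0.49, with the neutrophil chemokine CXCL5 at -0.83 ± 0.32 (48131 ± 7287 in Input, 27209 ± 4924 in miR-CLIP), the growth factor EREG at -0.94 ± 0.40, the chemokine CCL20 at -1.70 ± 0.72 and CXCL8, or interleukin-8, at -1.58 ± 0.77. The 20 microRNA pathway genes had a median of 0.55. Of these, EDC4 and DCP1A, which act in mRNA decapping, had 0.89 ± 0.33 and 0.68 ± 0.32, GEMIN4 had 0.76 ± 0.31, and the deadenylase CNOT7 went the other way with -1.18 ± 0.36.

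By camera with the preset correlation, the adjusted p was 7.50e-08 for the histone genes and 0.0223 for each of the other 2 lists. With an estimated correlation it was 0.727 for all 3, and fry gave an adjusted p of 0.675 for each, so none of the 3 calls held in those tests. In the limma test of all 6 libraries with group as the only term, no member of any list passed at adjusted p 0.05, adjusted over all genes or adjusted over the list alone. Library medians differed as widely. Histone genes had -1.73, 0.46 and -3.24 in miR-CLIP A, B and C and 1.16, 0.22 and -1.43 in Input A, B and C. SASP genes had -1.25, 0.32 and -0.55 in miR-CLIP A, B and C, and microRNA pathway genes 0.89, -0.35 and 0.80. Without miR-CLIP library B, 0 histone genes were higher and 37 lower, 1 SASP gene was higher and 12 lower, and 11 microRNA pathway genes were higher and 3 lower. Adjusted over the list alone, these were 0 and 47, 1 and 18, and 14 and 3. Histone genes are near-identical copies, so the assignment of reads among them is uncertain. After correction for GC content and transcript length, chosen after seeing the data, the camera adjusted p with the preset correlation was 4.89e-06 for histone genes, 0.249 for SASP genes and 0.0813 for microRNA pathway genes. Over the alternatives run with the preset correlation it ran from 4.63e-15 to 0.00387, from 0.00196 to 0.545 and from 9.36e-05 to 0.306.

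**Figure D3:**
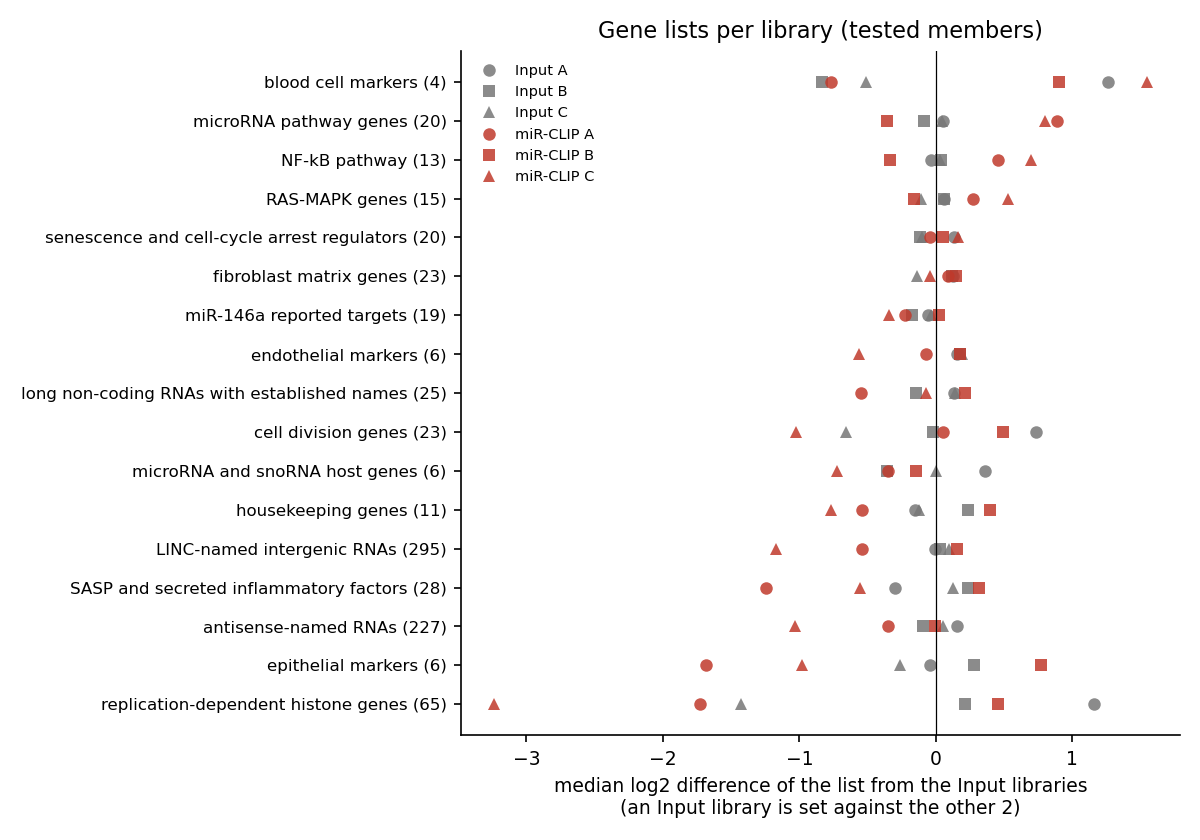
Median log2 difference of each tested list from the Input libraries (horizontal axis), 1 point per library, Input in grey and miR-CLIP in red, with the number of tested members beside each list. Histone genes sit at -1.73 and -3.24 in miR-CLIP A and C and at 0.46 in miR-CLIP B, while the Input points of that list reach from -1.43 to 1.16.

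None of the signalling lists that bear on miR-146a and RAS passed by camera in the main fit of all 6 libraries. Few of their members with initials M to Z were in the table, so these results cover a part of each list and not the whole pathway. The 19 tested members of the list of reported miR-146a targets had a median of -0.14, 8 positive and 11 negative, and a camera adjusted p of 0.913. Besides IRAK1, the NF-kB adaptor CARD10, with 1 site in its 3′ UTR, had 1.53 ± 0.70, the death receptor FAS, which overlaps the neighbouring ACTA2, -0.56 ± 0.28 and the phosphatase CDKN3 -2.04 ± 1.12. The 13 NF-kB pathway genes had a median of 0.32 (camera adjusted p 0.106), with the kinase IKBKE at 0.82 ± 0.31, IKBKG at 1.05 ± 0.42 and the apoptosis inhibitor BIRC3 at -0.80 ± 0.37. The 15 RAS-MAPK genes had a median of 0.16 (camera adjusted p 0.0758), with the ERK phosphatase DUSP5 at 1.23 ± 0.51, the phosphatase DUSP1 at 0.77 ± 0.42, the receptor EPHA2 at 0.45 ± 0.25 and the transcription factor ETV1 at -0.65 ± 0.31. The 20 senescence and arrest regulators had a median of 0.12 (camera adjusted p 0.476), with the antiproliferative gene BTG2 at 2.06 ± 0.63, and with HMGA1 at -1.52 ± 0.60, HMGB1 at -0.86 ± 0.41 and GADD45A at -0.69 ± 0.34. Without miR-CLIP library B, 3 reported targets were higher and 3 lower, 6 NF-kB pathway genes were higher and 1 lower, 3 RAS-MAPK genes were higher and 1 lower, and 4 senescence regulators were higher and 4 lower. In that fit the lists of NF-kB pathway and RAS-MAPK genes had a camera adjusted p of 0.0131 each. With an estimated correlation these became an adjusted p of 0.495 each. Over the camera alternatives with the preset correlation the adjusted p ran from 0.0131 to 0.623 for NF-kB pathway genes and from 0.0131 to 0.587 for RAS-MAPK genes, and with an estimated correlation and all 6 libraries it was 0.727 for both.

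Lists that describe the cells themselves gave no call with all 6 libraries. The 11 housekeeping genes had a median of -0.40 (camera adjusted p 0.106), with GAPDH at -1.65 ± 0.86, ACTB at -1.02 ± 0.51, B2M at -1.01 ± 0.46 and ENO1 at -0.86 ± 0.51. GAPDH had 8125, 101580 and 9560 normalised read counts in miR-CLIP A, B and C and 62584 ± 7725 in Input. Without miR-CLIP library B, 0 housekeeping genes were higher and 6 lower, with a median of -0.92 and a camera adjusted p of 0.00625, which was an adjusted p of 0.495 with an estimated correlation. Over the camera alternatives with the preset correlation the adjusted p ran from 0.00625 to 0.537, and with an estimated correlation and all 6 libraries it was 0.727. The 23 fibroblast matrix genes had a median of 0.07 (camera adjusted p 0.248), with ELN at 1.75 ± 0.80, COL3A1 at 0.89 ± 0.41, COL5A2 at 0.72 ± 0.33 and FBLN5 at -0.64 ± 0.34. The 23 cell division genes had a median of -0.29 (camera adjusted p 0.506), with CENPE at -0.90 ± 0.34, CDK1 at -1.26 ± 0.66, CDT1 at -0.80 ± 0.67 and AURKA at -0.43 ± 0.40. Their library medians were 0.73, -0.02 and -0.66 in Input A, B and C and 0.05, 0.49 and -1.03 in miR-CLIP A, B and C. Among markers of other cell types, CLDN5 had 164 ± 50.3 and CLDN4 45.7 ± 12.3 in Input, EPCAM 9.38 ± 4.82 and KRT8, which overlaps a neighbouring keratin gene, 111 ± 11.9, KDR had 22.2 ± 6.30, CDH5 12.8 ± 3.58, CSF1R 5.10 ± 3.42 and ITGAM 0.408 ± 0.707. Their log2 fold changes were -2.05 ± 0.83 for EPCAM, -1.09 ± 0.77 for KRT8, -1.35 ± 0.71 for KDR, 0.48 ± 0.62 for CDH5, 1.14 ± 0.70 for CSF1R and 1.45 ± 1.00 for ITGAM. KRT19 had -1.36 ± 0.99, CLDN4 0.35 ± 0.44, ERG 0.20 ± 0.54, CLDN5 -0.34 ± 0.47, CD14 -1.21 ± 0.95 and CD68 0.16 ± 1.04. The lists of epithelial, endothelial and blood cell markers had camera adjusted p of 0.476, 0.873 and 0.476.

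For lncRNAs, which the series title names, 0 of 1369 tested were higher and 0 lower at a limma adjusted p of 0.05, as for the 6350 protein-coding genes, so Fisher's exact test of the difference had no calls to compare. At an unadjusted p under 0.05, 15 lncRNAs were higher and 76 lower. Of those chosen after their values were seen, JHDM1D-AS1 (chromosome 7, 140177261 to 140179640) had 25.2 ± 3.84 in Input and 83.7 ± 37.1 in miR-CLIP, a log2 fold change of 1.60 ± 0.50, BACH1-IT2 had 2.24 ± 0.78 and LINC01004 had 1.41 ± 0.55. BACH1-IT2 and LINC01004 were low in Input, at 3.76 ± 2.69 and 6.62 ± 1.17. LINC01351, FRY-AS1 and ACAP2-IT1, and LINC00601 from the list of LINC-named RNAs, had 2.71 ± 0.853, 2.52 ± 0.0784, 2.23 ± 0.426 and 2.03 ± 0.5 in Input and no read in any miR-CLIP library. These Input values lie at a few reads per library, so no fold is given. CDR1-AS, a circular RNA host locus (chromosome X, 140783176 to 140784660), had -2.26 ± 0.73, from 3900 ± 1735 to 1198 ± 1388, DLGAP4-AS1 had -2.06 ± 0.74 and LINC01278 -3.20 ± 1.19. The counts do not state a strand, so reads of antisense RNAs and their partner genes cannot be told apart here.

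The 295 LINC-named RNAs had a median of -0.43 (camera adjusted p 0.106), with LINC00707 at -1.95 ± 0.70, the 227 antisense-named RNAs -0.49 (0.0796), the 25 lncRNAs with established names -0.26 (0.814) and the 6 microRNA and snoRNA host genes -0.40 (0.736). Over the camera alternatives with the preset correlation the adjusted p ran from 0.018 to 0.764 for LINC-named RNAs and from 0.018 to 0.526 for antisense-named RNAs. Both lists passed with upper-quartile factors, and the antisense-named list also without Input B (camera adjusted p 0.0375). With an estimated correlation and all 6 libraries the camera adjusted p was 0.727 for both. Among established names, the imprinted KCNQ1OT1 had 1.78 ± 0.78, JPX -1.02 ± 0.55, LINC00473 -2.14 ± 0.86 and LINC00968 -1.48 ± 0.84. LINC00707, LINC00473 and LINC00968 were low, with 4.70 ± 1.45, 7.45 ± 1.21 and 4.14 ± 1.07 in Input and no read in miR-CLIP A and C. In miR-CLIP B they had 1.99, 5.96 and 4.96, so their folds are uncertain. Among the host genes, C1orf132 had 0.73 ± 0.62, C1orf204 0.53 ± 0.76 and GAS5, a snoRNA host, -0.03 ± 0.47. The class median of lncRNAs was -0.42, and that of coding genes at the same mean level -0.45. Taken library by library, the median of lncRNAs lay 0.08 ± 0.20 (SD, n = 3 miR-CLIP libraries) above that of matched coding genes, less than the spread. Library medians of lncRNAs were -0.38, 0.05 and -1.04 in miR-CLIP A, B and C. Without miR-CLIP library B, 32 lncRNAs (2.34%) and 1024 protein-coding genes (16.1%) were higher, and 158 lncRNAs (11.5%) and 1147 protein-coding genes (18.1%) were lower. For calls higher, Fisher's exact test across genes gave an odds ratio of 0.124 and p of 1.92e-55 there. The odds ratio was 0.271 with edgeR without that library, 0.358 after the GC and length correction without it and 0.109 with library weights, with p up to 5.27e-12. These tests did not match genes on mean level, and without library B lncRNAs were also called lower less often with limma. They cannot tell a weaker capture of lncRNAs from a smaller chance of a call.

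Protein-coding genes with a miR-146a site in the 3′ UTR stood higher in miR-CLIP than those without one. The 771 genes with AGTTCTC had a mean log2 fold change of 0.06 and the other genes of the 6294 searched -0.19, a difference of 0.24. It was above all 299 control 7-mers, whose middle 95% lay between 0.05 and 0.18, and the two-sided rank p of 0.00667 is the smallest those controls can give. By library, the difference from the Input libraries was 0.45 in miR-CLIP A and 0.52 in C, each above 100% of control 7-mers, and -0.24 in miR-CLIP B, above 66.2% of them. Over the 3 miR-CLIP libraries it was 0.24 ± 0.42 (SD, n = 3), so the difference itself was smaller than the spread between libraries. The same value had an SD of 0.06 among the Input libraries, where Input A lay above 99.7% of controls and Input C above 0.669% (rank p 0.0133 and 0.02). The rank p can thus be small between Input libraries too, and it measures spread over 7-mers, not over libraries.

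Of the other forms of the site, the 6mer GTTCTC, in 2082 genes, gave 0.23, above all 39 of its controls (rank p 0.05, the smallest these can give). The 7mer-A1 site GTTCTCA, in 917 genes, gave 0.19 (rank p 0.0267), and the 8mer AGTTCTCA, in 290 genes, 0.22 (rank p 0.00952). In coding sequence, 765 genes with AGTTCTC gave 0.23 (rank p 0.0667), and the 7mer-A1, 8mer and 6mer lay above 63.9%, 91.1% and 71.8% of controls (rank p 0.727, 0.179 and 0.6). In 1348 tested lncRNAs searched over the whole of their longest transcript, 152 had AGTTCTC, and the difference of 0.12 lay above 54.8% of control 7-mers (rank p 0.907). Without miR-CLIP library B it lay above 66.6% of them.

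**Figure D4:**
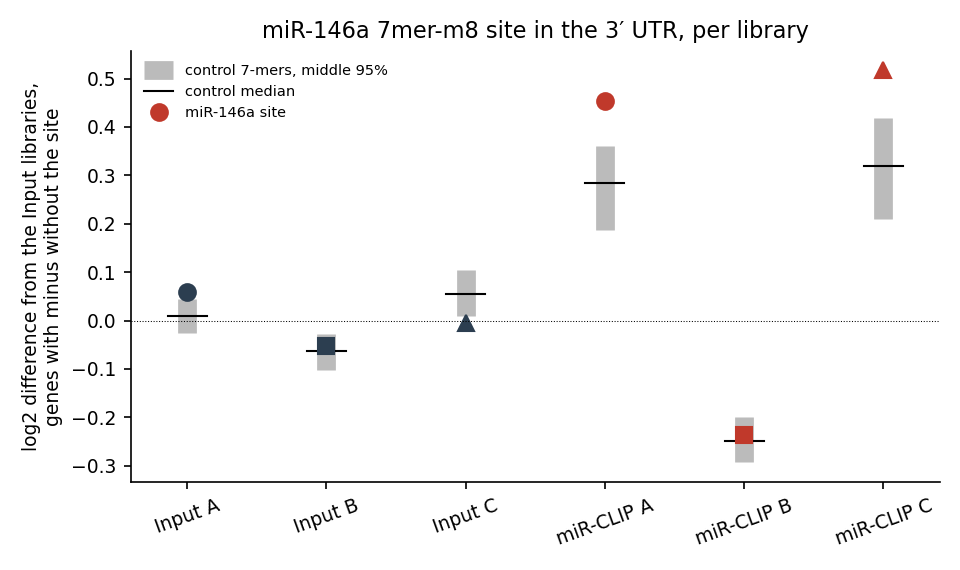
Mean log2 difference from the Input libraries of genes with minus without a miR-146a 7mer-m8 site in the 3′ UTR (vertical axis), 1 point per library, with the middle 95% of 299 control 7-mers in grey and their median as a black line. The points of miR-CLIP A and C, at 0.45 and 0.52, lie above their grey range, and that of miR-CLIP B, at -0.24, lies within it.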

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

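The count of genes past adjusted p 0.05 was 0 in 20 alternatives, among them edgeR, DESeq2, limma-voom, all scalings, all pseudocounts and both filters, and rose when miR-CLIP library B was left out or given less weight. Leaving out each library in turn gave between 0 and 2442 genes and between 0 and 32 lncRNAs called higher, where 2442 and 32 came from the fit without miR-CLIP library B and each other library gave 0. Chosen after seeing the data, edgeR without that library called 2407 genes and 36 lncRNAs higher, the correction for GC content and length without it 1873 and 39, and library weights, in which library B received 0.159, 1243 and 13. Of the 2442, 1434 were also called in the same direction after the correction. The deposited scaling put the median log2 fold change of tested genes at -0.13, library size alone at -0.27 and upper-quartile factors at 0.06.

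The number of lists past a camera adjusted p of 0.05 was 3, 6 with upper-quartile factors, 1 after the GC and length correction, 0 with an estimated correlation and 0 with fry. It was between 1 and 6 when each library was left out, with 1 without miR-CLIP A and 6 without miR-CLIP B. The site difference was between 0.11 and 0.49 leaving out each library, with 0.49 without miR-CLIP B, and above all 299 control 7-mers in 19 of 19 settings of the fit, 0.10 to 0.51. These settings refit the same libraries, so they are not independent support. It missed the threshold for the 6mer (0.23, rank p 0.05, the smallest its 39 controls can give) and in coding sequence (0.23). The cause was not tested.

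Leaving out 1 library gave values on both sides of 0, for list medians relative to the median of tested genes in cell division genes (-0.41 to 0.30), endothelial (-0.35 to 0.18) and epithelial markers (-1.10 to 0.0772), established lncRNAs (-0.37 to 0.0585), reported targets (-0.14 to 0.18), and for plain log2 fold changes in C1orf204 (-0.23 to 1.10), CD68 (-0.42 to 1.31), CLDN5 (-0.66 to 0.0618), ERG (-0.0139 to 0.43) and GAS5 (-0.59 to 0.33). The sign also turned for targets with upper-quartile factors (0.0097), and after the GC and length correction for endothelial markers (0.0153), matrix genes (-0.15) and host genes (0.10). With the correction and no library B it turned for ACAP2-IT1 (0.17, a product of the correction, since the gene has no miR-CLIP read), C1orf132 (-0.50), CD68 (-0.17) and ERG (-0.19). CD68 also turned with a pseudocount of 0.1 (-0.64) and library weights (-0.40), ERG after the correction alone (-0.0851), and GAS5 with upper-quartile factors (0.18), edgeR (0.16), DESeq2 (0.17) and the correction (0.27).

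A replicate block by column letter called 0 genes, and, adjusted over the list alone, 6 histone genes lower and 1 senescence regulator higher, where the main test called 0. Libraries of the 2 groups share letters, and r of same-letter deviations from the group mean was 0.140, 0.107 and 0.0857. For different letters it ran from -0.0832 to -0.0410, so every library correlated best with its own letter. The labels state no pairing, so the main test did not treat libraries as paired, but a pairing by letter is not excluded.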

Other observations

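The tests of exchanged labels, of library B as a further Input library, of 3′ UTR length and composition, of transcript length and of dividing cells, and the split of the gene count, were chosen only after the results they bear on were seen.

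The genes of this paragraph were chosen after their values were seen and stand for no group. The cytokine gene IL1B had 49979 ± 12301 normalised read counts in Input (SD, n = 3), IL6 1586 ± 246, IL1A 1371 ± 88.7, CXCL1 5672 ± 1807, LIF 4227 ± 460 and GDF15 3529 ± 683. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had 29753 ± 4788, CDKN2B 867 ± 123 and CDKN2A 578 ± 8.64. The ERK phosphatase DUSP6 had 6943 ± 323 in Input and 6815 ± 360 in miR-CLIP, while LIF had 7101 ± 3087 and CDKN1A 53532 ± 23699 in miR-CLIP.

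4 further genes were picked because their values were high in miR-CLIP A and C and not in B, a pattern that many genes shared, since 1069 were called higher without B. The BH3-only genes BBC3 and BMF had 95.2 ± 19.4 and 1444 ± 262 in Input. BBC3 had 391, 117 and 641 and BMF 5931, 1598 and 9647 in miR-CLIP A, B and C. The decapping enzyme DCP2 had 521 ± 108 in Input and 1837, 330 and 3036, and the interleukin-6 receptor IL6R 439 ± 74.7 and 1548, 459 and 2607.

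The first pattern weighed was that miR-CLIP library B lay with the Input libraries. An exchange of labels with an Input library would need an Input library closer to miR-CLIP A and C than to the other Input libraries, but the largest such difference in mean r was -0.0425. A further Input library under this label would be expected to show the Input relation to transcript length, and library B had a Spearman correlation of -0.372 where the Input libraries had -0.107 to 0.0477, although with GC content its correlation of 0.361 lay close to their range of -0.352 to 0.309. If B mixed captured with uncaptured RNA, its differences would follow those of miR-CLIP A and C, but the slope was negative in all 6 fits that divided the Input libraries, before and after the GC and length correction, the highest being -0.0677. Library B also had a length trend opposite to that of A and C, but the slopes after that correction, -0.128, -0.0677 and -0.107, were negative too. The length trend that the correction removed thus does not account for them. A small captured share is not excluded by these slopes, since other differences of library B could hide it. A failed capture with its own RNA loss, or a library from elsewhere, may remain as explanations and were not tested, and the design names no biological difference between the 3 libraries.

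The second pattern was the higher standing of genes with a miR-146a site. Removal of 3′ UTR length and GC share shrank the difference from 0.24 to 0.106, and correction for transcript length and GC content to 0.0967, both above all 299 control 7-mers. The control medians shrank alike, so the excess over them went from 0.126 to 0.0973 and 0.0931, which argues against UTR length and composition as the whole cause. Targets that AGO2 holds through other microRNAs would be expected to give like values for other sites, and the excess of the miR-146a site over its control median, 0.126, was above that of all 14 other microRNA sites tried, whose mean was 0.03 ± 0.03 (SD) and whose highest, let-7, reached 0.0747. Since let-7 itself lay above 99.0% of its control 7-mers (rank p 0.0381), a part from AGO2-bound RNA in general may be present. The other sites cannot tell capture through the mimic from AGO2 binding through the cells' own miR-146a, since both have the same site. Binding of the transfected mimic to these mRNAs remains a hypothesis, and the difference lay above all control 7-mers in miR-CLIP A and C and not in B. Over the 10 splits of the 6 libraries, the real excess was 0.126 and the highest other 0.140, with 2 splits at 0.126 or more counting the real one, and 10 splits are too few for a share under 0.05. The split that gave 0.140 set miR-CLIP A and C with an Input library against miR-CLIP B and the other 2.

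The third pattern was the lower standing of histone genes. Transcript length and base composition as the whole cause is argued against by the corrected median of -1.37. Loss of low-count transcripts in the miR-CLIP libraries would be expected to lower other genes of that level alike, but the histone median minus the median of 1000 sets of matched genes was -1.40, and the lowest set had a median of -0.50 against -1.56. Fewer dividing cells stay open: cell division genes lay 1.34 ± 1.15 (SD, n = 3 miR-CLIP libraries) above the histone genes, but by only 0.04 in B, and both lists had their highest Input median in A and their lowest in C (0.73 and -0.66 for cell division genes, 1.16 and -1.43 for histone genes). Variation between libraries may also account for the pattern, since the estimated correlation between members was 0.638.

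For the number of genes past the threshold, the real split gave 0 and the highest other 0, so all 10 splits count as large by construction and the comparison decides nothing. For the number of lists, the real split gave 3 and the highest other 8, with 6 of 10 splits at 3 or more, again too few splits for a share under 0.05. The splits that called 6, 7 and 8 lists were those that put miR-CLIP A and C on the side opposite to miR-CLIP B, which points to the structure of the libraries described above.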
